A study of Mus musculus with 2 samples.

How the data were processed

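H3K27ac ChIP-seq was done on hearts of mouse embryos at 10.5 days of gestation in 2 biological replicates, which form 1 group. Chromatin fragments were 300 to 500 bp long per the labels. Per the deposited text on file origins, the authors called peaks on each replicate's alignments with its control, called a pooled list on both replicates and both controls together, and derived the replicated list from the pooled list and both replicates' lists. All lists are on mm10. The peak caller and its version, and the rule that made the replicated list, are not given in the sources used here.

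The deposited narrowPeak files give, as the authors' values, a signal for each peak, whose scale is not given in the sources used here, and the −log10 p of the peak. The lowest −log10 p was 2.00 in replicate 1 and 2.02 in replicate 2, and 46.5% and 48.9% of their peaks lay under 5. The offset of the summit, also deposited, was used to place motif windows. Signal was compared only within one list, to rank peaks, to weight clusters by signal times width, and to set medians of gene lists and chromosomes side by side. A −log10 p of at least 5 was applied to both replicates' lists as one alternative. Read counts are not in these files, so the depth of each replicate is unknown, and Wilson intervals for shares of peaks cover counting error only.

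Peaks on the 21 main chromosomes were used, and 7 replicated peaks on unplaced scaffolds were left out of the comparisons. No peaks overlapped within any list (0 in each), so merging changed nothing and every peak is a region. Of the 91850 replicated peaks, 75.1% overlapped peaks of both replicates, 20.0% replicate 2 only, 3.95% replicate 1 only and 0.904% neither. Gene models were those of GENCODE release M21 on GRCm38, the assembly of mm10, with 21911 protein-coding genes and 93472 TSSs. Where a symbol was used by several gene identifiers the first one was taken. Positions are printed counted from 1.

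A gene had a promoter peak when a peak overlapped the 1 kb to either side of one of its TSSs. Distal peaks lay over 1 kb from every TSS of a protein-coding gene and were assigned by their nearest TSS within 100 kb. For clusters, distal peaks within 12.5 kb of each other were joined, ranked by the sum over peaks of signal times width, and the 500 highest were kept. A cluster was assigned to the TSS nearest to its midpoint without a distance limit. The cluster at rank 5 lay 168083 bp from its nearest gene, Zfp36l1. Motifs were counted on both strands within 250 bp of the summit of distal peaks and in windows of equal size 5 kb to either side that overlap no peak of any list. The GC content was 50.6% in peak windows and 44.5% in flanks, and anagrams of each consensus (up to 200, with equal CpG number) served as its reference.

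The lists and the rule for named genes were set before the data were examined, as were the comparisons and the alternatives, except for those said to be added. The 19 gene lists hold 344 entries of 338 distinct genes, and 1 further gene, Ahsp, was not found among the annotation's symbols. Other lists also hold 3 of the 28 cardiac transcription factors, 2 of the 20 cushion genes, 4 of the 17 second heart field genes and 3 of the 18 secreted signals. Named genes were 32 fixed markers, up to 4 members of each list with the highest promoter signal and up to 4 without a promoter peak in alphabetical order, the nearest genes of the 20 highest-ranked clusters, and the 10 genes with the most distal peaks. Any other gene or region named was chosen after its values were seen.

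Promoter peaks of lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes. Distal peaks and clusters were tested with two-sided permutation tests against 10000 random lists of the same size, drawn with replacement and matched on decile of the width of the gene's nearest-TSS domain. Their smallest p is 0.0002. Domain width was taken within the distance limit of distal peaks. Clusters have no such limit, so room beyond it was not matched for them. Motifs were ranked among their anagrams, two-sided, with a smallest p of 0.00995 for 200 anagrams, 0.0667 for the 29 of GATA and 0.143 for the 13 of homeobox. All p were adjusted by Benjamini-Hochberg over the 19 lists or motifs at a threshold of 0.05. Genes are not independent replicates, so these p describe the peak lists and not a variation between animals. Neighbouring genes of one list, such as Hox genes, were treated as separate draws, so the p of such lists may be too small. To match on promoter sequence, random lists were also drawn by decile of the CpG ratio within 500 bp of TSSs or of the number of annotated TSSs.

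The tests of promoter peaks, distal peaks and motifs were tested on simulated data, and the other methods were not. With no change, 0.351% of 1140 lists were called for promoter peaks and 0.263% of 380 for distal peaks. The simulated lists were random genes, and promoter peaks were given at random without regard to CpG ratio or TSS number. These rates therefore do not cover calls that such differences between real lists bring. Promoter shares raised to 98% were called in 91.1% of 360 lists and shares lowered to 30% in 76.1% of 360. Distal counts doubled in the mean were called in 25.0% of 120 lists, so a change of that size is often missed. Of 5 planted motifs 4 were called, and of 14 not planted 0. The planted motif not called, GATA, has too few anagrams to pass. All were planted together, which gave the 4 low p that a call needs. The simulation therefore does not show that fewer enriched motifs would be called. Its peak windows and flanks were random sequence of equal base composition, whereas the real ones differ in GC content.

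The alternatives tried were peaks at or above the median signal, a −log10 p of at least 5, the 20000 highest-ranked peaks, equal peak numbers, an overlap of 50% of both regions or of either, the pooled list, and each replicate's own list at the size of the replicated list, which leaves out the other replicate. Further ones were promoter windows of 500 bp and 2 kb, 1 TSS per gene, covered bases in place of peaks, limits of 50 and 500 kb, genes with a promoter peak only, stitching distances of 5 and 25 kb, 250 and 1000 clusters, ranking by covered bases, motif windows of 100 and 500 bp, and peak midpoints. Added after seeing the data were replicated peaks that overlap both replicates' lists and a distal class counted from TSSs of every gene type. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.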

Results

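The data map H3K27ac, a histone acetylation carried by active promoters and enhancers, by ChIP-seq in the embryonic mouse heart at 10.5 days of gestation. There was 1 group of 2 biological replicates from strain B6NCrl, each a pool of hearts of mixed sex. Replicate 1 pooled 69 embryos and replicate 2 pooled 51. The list of replicate 1 held 131819 peaks, and that of replicate 2 held 177918. A list called on the pooled alignments held 200585 peaks, and 91857 of them formed the authors' replicated list, with a median width of 616 bp and 3.20% of the genome covered. Read counts are not in the files, so the sequencing depth is unknown. The number of peaks or genes behind a value sets its counting error only, and the spread between biological samples rests on the 2 replicates. Peak signal and −log10 p are the authors' values, and signals were compared only within one list. Each gene or region has 1 value in the replicated list, without a replicate error, so the replicates' own values stand beside the shares and means.

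Hand2, a transcription factor needed for the right ventricle, lay under one of the widest peaks of the replicated list, 25422 bp long at 8:57311541-57336962 in mm10 (signal 27.8). The widest peak of the replicates' own lists there measured 12160 bp in replicate 1 and 14221 bp in replicate 2. From 60 kb before the gene to 60 kb after it, the lists held 23 peaks in replicate 1, 20 in replicate 2 and 10 in the replicated list. The promoter peaks of Nkx2-5, Gata4, Tbx5 and Tbx20, the core transcription factors of cardiac muscle, each overlapped a peak of both replicates. Those of Myh6 and Myh7, the myosin heavy chains of atrium and ventricle, did so too. Sox2, a factor of neural progenitors, had a promoter peak in each replicate's own list and none in the replicated list.

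**Figure D1:**
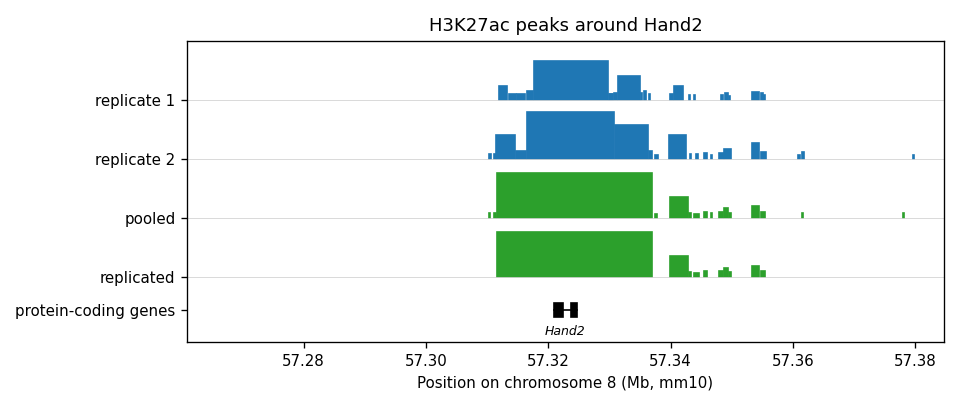
Map of the region around Hand2 on chromosome 8 (x axis, position in Mb, mm10), with one row per peak list, box height in proportion to the peak's signal, and the gene with its exons at the bottom. The replicated list has 10 peaks here, and the widest of them spans 25422 bp over the gene.

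The question of this comparison was how far the 2 replicates' peak lists coincide. Of the replicate 1 peaks on the main chromosomes, 71.7% (94531 of 131811, 95% Wilson interval 71.5 to 72.0%) overlapped a replicate 2 peak by at least 1 bp. In the other direction the share was 44.2% (78635 of 177907, interval 44.0 to 44.4%). Circular shifts of the other list gave 6.22% ± 0.313 (SD of 100 shifts) and 4.53% ± 0.234. Peaks within 1 kb of a transcription start site (TSS) overlapped in 86.7% and 70.96% of cases, and distal peaks in 67.8% and 39.1%. In the highest decile of signal 100% and 99.8% of peaks overlapped, and in the lowest decile 55.9% and 22.5%. The share moved by over 1.5 times when 50% of both regions had to be shared (31.0% and 23.0%), and replicate 2 in replicate 1 reached 80.7% among its 20000 highest-ranked peaks.

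**Figure D2:**
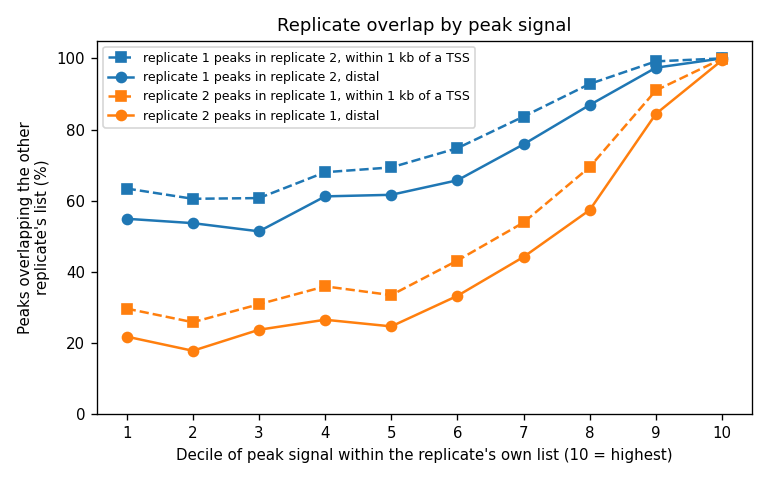
Share of one replicate's peaks that overlap the other replicate's list (y axis, %) by decile of peak signal within its own list (x axis, 10 is highest), with dashed lines and squares for peaks within 1 kb of a TSS, solid lines and circles for distal peaks, and one colour per direction. In the highest decile 100% of replicate 1 peaks and 99.8% of replicate 2 peaks overlap, against 55.9% and 22.5% in the lowest.

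Several cardiac regulators lay under the 25 widest peaks of the replicated list. Zfpm1, a cofactor of GATA factors, carried a peak of 30932 bp at 8:122295953-122326884, and Unc5b, a netrin receptor of vessels, one of 29454 bp at 10:60802810-60832263. Peaks of Meis1 (17321 bp), Gata4 (17079 bp at 14:63236452-63253530), Mef2d (15591 bp), Gata5 (15168 bp), Gata6 (14244 bp) Meis2 (13264 bp) and Tbx5 (13001 bp) were also among them, with that of Hand2. The others were promoter peaks at Lsp1, Irf2bpl, Mical2, Zmynd8, Ddc (2 peaks), Tnrc18, Ahdc1, Skida1, Actn4, Ptp4a3, Slc41a3 and Kdm6b, and 2 intergenic peaks nearest to Il17b and Mrpl23. The widest peak anywhere in replicate 1's own list measured 12160 bp and that in replicate 2's 27329 bp. No peak of replicate 1 was therefore as wide as these 25. The highest signals lay at the promoters of Kmt5b, a histone methyltransferase (48.4), Arrdc3 (45.9), Actg1, a cytoplasmic actin (45.5), Epc1 (45.1) and Ddx6 (43.8), followed by an intergenic peak nearest to Chd2 (43.6). Intergenic here means outside protein-coding genes, so noncoding genes may lie at such peaks. These wide and high peaks were chosen after their values were seen.

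Where the peaks lie relative to genes was compared with the genome's own make-up. Promoters, taken as 1 kb to either side of a TSS of a protein-coding gene, held 22.1% of replicated peaks (20289 of 91850) against 3.59% of the genome's bases, a ratio of 6.15. Exons held 6.91% of peaks (ratio 2.69), introns 37.9% (ratio 1.16) and intergenic sequence 33.1% (ratio 0.541). Classes were built from protein-coding genes only. Each peak was counted in 1 class, by any overlap, in the order promoter, exon, intron, intergenic. By covered bases, in the same order, the ratio was 8.03 for promoters, 1.34 for exons (3.44% against 2.57%), 1.17 for introns and 0.481 for intergenic sequence. In the same number of highest-ranked peaks of each replicate the promoter share was 24.9% and 22.6% (mean 23.8% ± 1.60, SD, n = 2). It was 34.1% among peaks at or above the median signal and 14.6% in the pooled list, which moved it by over 1.5 times each.

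Every one of the 28 cardiac transcription factors on the list had a promoter peak, as had all 28 sarcomere genes, all 24 endocardial and endothelial genes, all 12 epicardial genes and all 18 secreted signals of heart development. By contrast 4 of 15 macrophage and leukocyte genes, 7 of 18 neural genes, 4 of 16 posterior Hox genes and 8 of 21 genes of other adult tissues had one. Over all protein-coding genes the share was 66.2% (14503 of 21911). The question was which cell types' genes carry the mark at their promoters in this tissue.

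Among the cardiac transcription factors the highest promoter signals were those of Mef2a (32.9), Meis1 (31.2), Tead1 (30.8) and Hand2 (27.8). Nkx2-5 had a peak of 10795 bp at 17:26836070-26846864 (signal 20.2), Gata4 one of 9381 bp at 14:63264338-63273718 (signal 21.3), and Tbx5 one of 13001 bp at 5:119827972-119840972 (signal 21.3). Tbx20, which keeps chamber myocardium proliferating, stood at 16.4, Mef2c, a MADS-box activator of muscle genes, at 14.9 and Isl1, a marker of second heart field progenitors, at 10.4. The median promoter peak of this list was 6628.5 bp wide at percentile 94.3 of signal, against 1665 bp and percentile 92.4 over all genes with a promoter peak. In the replicates' own lists its median width was 2996 bp in replicate 1 and 5921.5 bp in replicate 2, against 1151 and 1471 bp. Random lists matched on promoter CpG ratio had a mean share of 89.6%, and against them the list did not pass (adjusted permutation p = 0.109).

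Sarcomere genes, which encode the contractile apparatus, included Myl7, the atrial light chain (9543 bp at 11:5890466-5900008, signal 17.9), and Myh7 (10683 bp at 14:54988756-54999438, signal 17.4). Tnnt2, cardiac troponin T, stood at 14.0, Actc1, cardiac actin, at 13.5, Myh6 at 13.1 and Myl2, the ventricular light chain, at 10.5. The list's highest signals were those of Myom1 (36.4), Tnnc1 (25.9), Myl3 (23.7) and Tpm1 (22.7), where the first 3 peaks also covered a TSS of Myl12a, Nisch and Pth1r. CpG-matched random lists had a mean share of 48.5% (adjusted permutation p = 0.00076 against them).

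For ion handling and conduction, 23 of 24 genes had a promoter peak, led by Gjc1 (31.6), a connexin, Atp2a2 (28.5), the calcium pump of the sarcoplasmic reticulum, Kcnh2 (26.2) and Id2 (25.9). Ryr2, the calcium release channel, stood at 19.4 and Hcn4, the pacemaker channel, at 14.9. Nppa and Nppb, the natriuretic peptides, stood lower at 6.96 and 7.10, and Sln, which encodes sarcolipin, had no peak. Endothelial promoters had moderate signals, with Egfl7 at 13.2 (a peak that also covered a TSS of Gm20532), Nfatc1, a factor of endocardial cushions, at 11.9, Notch1 at 10.3, Pecam1 at 9.11 and Kdr, a VEGF receptor, at 8.13. Epicardial promoters included Bnc2 (14.1), Tbx18 (12.54), Tcf21 (10.5), Bnc1 (6.55) and Wt1 (5.11). In the cushion and mesenchyme list 19 of 20 genes were marked, led by Vcan (18.7), Twist1 (15.3), Tgfb2 (11.8) and Msx2 (11.3). Postn, a matrix protein of cushions, stood at 3.52, and Dcn had a peak in each replicate's list but not in the replicated list. Second heart field genes were marked in 16 of 17 cases, with Wnt5a at 19.7 and Foxc1 at 17.7, and Nkx2-6 had none. Vegfa (28.3), Igf2 (27.2), Jag1 (26.0) and Tgfb3 (13.9) led the secreted signals.

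Of the primitive erythroid genes 14 of 16 had a promoter peak, led by Klf1 (12.7), Nfe2 (12.7), Tal1 (12.6) and Gypa (8.15). With an equal number of each replicate's own peaks, 10 were marked in replicate 1 and 13 in replicate 2. Fisher's exact test did not call this list, whereas CpG-matched random lists had a mean share of only 28.6% (adjusted permutation p = 0.00076 against them). The embryonic globins Hbb-y (4.15) and Hba-x (4.47) had promoter peaks, and the adult globins Hba-a1 and Hba-a2 had none. Read mapping at Hba-a1 and Hba-a2 was not examined, so their lack of a peak does not show a lack of the mark. Ptprc, the pan-leukocyte antigen, Adgre1 and the complement genes C1qa, C1qb and C1qc had no promoter peak, while Runx1 (10.2), Spi1 (4.79), Laptm5 (3.99) and Aif1 (2.72) had one. Of the neural list Foxg1, Neurod1, Neurog1, Neurog2 and Sox2 were without a peak in the replicated list, and Elavl3 (4.63), Dlx2 (4.40), Dlx1 (4.29) and Pax6 (3.36) had low ones.

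Neural crest genes were marked in 8 of 12 cases, with Mpz at 19.97 (a peak that also covered a TSS of Sdhc), Ets1 at 12.4, Erbb3 at 7.51 and Ednrb at 6.96, and none at Foxd3, Pax3, Phox2b or Tfap2b. Foregut and pharyngeal endoderm genes had a peak in 10 of 14 cases, with Krt18 (9.23), Grhl2 (7.61), Krt8 (6.78) and Epcam (4.47) but not Pax1, Pax8, Pax9 or Shh. In the hepatocyte list Prox1 (20.6), Foxa3 (18.2, shared with Sympk), Hhex (9.08) and Cebpa (7.51) were among 8 of 15 genes with a peak, and Alb, Afp, Apoa1 and Apob had none. In the skeletal muscle list 6 of 12 had one, with Ckm (10.6), Myl1 (8.15), Myog (4.75) and Lbx1 (3.66), and Myod1, Myf5, Myh3, Myh8 and Chrna1 had none. Anterior Hox genes, which pattern the hindbrain and pharyngeal arches, were marked in 12 of 12 cases, led by Hoxb2 (18.9), Hoxa1 (11.7), Hoxb3 (10.97) and Hoxb4 (10.9). The posterior genes with a peak were Hoxa10 (3.81), Hoxa9 (3.20), Hoxd9 (2.96) and Hoxd13 (2.37), and Hoxa11, Hoxa13, Hoxb9 and Hoxb13 were among the 12 without. All 22 housekeeping genes were marked, led by Ubc (34.5, shared with Gm10382), Rpl19 (34.4), Gapdh (34.1, shared with Ncapd2) and Rpl13 (34.0). Among genes of other adult tissues Dazl (10.8), a germ cell gene, Rho (3.89), Opn1sw (3.68) and Ddx4 (3.61) had a peak, and Amelx, Csn1s1, Csn2 and Cyp2e1 had none. Of the genes named as without a replicated peak, Neurog1 and Pax9, like Sox2 and Dcn, had one in each replicate's own list, Foxg1, Hoxa11 and Hoxb9 in replicate 1 only, and Pax1, Pax3, Tfap2b, Apoa1 and Hoxa13 in replicate 2 only.

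Two-sided Fisher's exact tests against all other protein-coding genes, adjusted by Benjamini-Hochberg over the 19 lists, called 10 lists above and 4 below. Adjusted p was 0.000185 for cardiac transcription factors and for sarcomere genes, 0.000595 for endothelium, 0.000719 for housekeeping genes, and 0.00248 for ion handling and for secreted signals. It was 0.00832 for cushion and mesenchyme, 0.0180 for epicardium and for anterior Hox genes, and 0.0258 for the second heart field. The 4 lists below were posterior Hox (0.00248), macrophage (0.00488), other adult tissues (0.0180) and neural (0.0301). Not called were erythroid (0.138), skeletal muscle (0.282), hepatocyte (0.322), endoderm (0.828) and neural crest (1). Against CpG-matched random lists, adjusted permutation p was 0.00076 for sarcomere, endothelial and erythroid genes, which lay above them, and for neural and posterior Hox genes, which lay below. Also above were epicardium (0.00317), cushion (0.00977) and ion handling (0.0142), and the other lists did not pass. The erythroid call was gained by this match (87.5% against 28.6%). Against random lists matched on the number of annotated TSSs, the calls of neural genes (38.9% against 55.2%, adjusted permutation p = 0.236) and posterior Hox genes (25% against 46.3%, p = 0.160) ended, and one was gained for erythroid genes (87.5% against 58.5%, p = 0.0272). With an equal number of each replicate's own peaks, 28 of 28 transcription factors and 28 of 28 sarcomere genes were marked in both.

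The call ended for epicardium without replicate 1 (75.0%, adjusted exact p = 0.623) and at the median signal (75.0%, p = 0.438), for cushion without replicate 2 (85.0%, p = 0.0855) and at the median signal (85.0%, p = 0.0501), for anterior Hox genes in 3 alternatives (91.7%, p from 0.0501 to 0.0914), for the second heart field with 1 TSS per gene (82.4%, p = 0.178), for neural genes in the pooled list (66.7%, p = 0.890) and in 2 kb windows (50%, p = 0.169), and in the pooled list for posterior Hox genes (50%, p = 0.140) and other adult tissues (52.4%, p = 0.140). Without replicate 1 the share fell to 6.25% for posterior Hox and 19.0% for other adult tissues, without replicate 2 it was 2 of 16 for posterior Hox, and a call was gained for skeletal muscle without replicate 1 (33.3%, adjusted exact p = 0.0441) and at the median signal (25%, p = 0.0226) and for erythroid genes in 2 kb windows (93.8%, p = 0.0428).

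**Figure D3:**
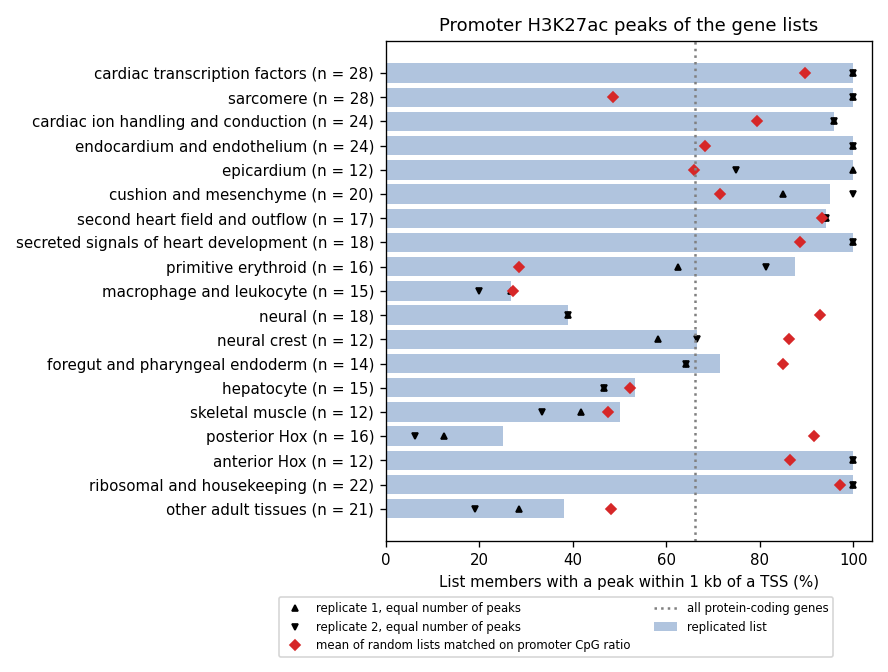
Share of list members with a peak within 1 kb of a TSS (x axis, %) for each gene list (y axis, n genes): bars for the replicated list, triangles for an equal number of each replicate's own peaks, red diamonds for the mean of CpG-matched random lists, and a dotted line at the 66.2% of all protein-coding genes. Cardiac transcription factors and sarcomere genes reach 100%, and posterior Hox genes stand at 25%.

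Distal peaks gathered around the genes of cardiac muscle and endothelium. Cardiac transcription factors had a mean of 22.2 distal peaks per gene, against 6.21 ± 2.07 (SD) in random lists matched on the width of the gene's domain. The mean was 14.3 for ion handling genes (random 4.76 ± 1.83), 11.2 for endothelial genes (3.96 ± 1.62) and 7.43 for sarcomere genes (2.32 ± 1.03). Posterior Hox genes had 0, against a random mean of 0.865.

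Tead1, a factor of the Hippo pathway, had 89 distal peaks and Prdm16, a regulator of compact myocardium, had 99. Gata4 had 27, Mef2c 19, Nkx2-5 18, Tbx5 16, Tbx20 16 and Hand2 10, whereas Isl1 had 1. With an equal number of each replicate's own peaks, replicates 1 and 2 gave 29 and 27 for Gata4 but 11 and 23 for Mef2c, 28 and 22 for Nkx2-5, 26 and 12 for Tbx5, 21 and 11 for Hand2 and 1 and 3 for Isl1. Ryr2 had 32 and Hcn4 had 25. In the endothelial list Nfatc1 had 35, Notch1 30, Kdr 24 and Pecam1 19. Sarcomere genes ranged from Tpm1 with 32 to Actc1 and Myl7 with 1 each, with Myl2 at 9, Tnnt2 at 7, Myh7 at 6 and Myh6 at 3. Nppb had 6 and Nppa 0. Tbx18 and Tcf21 had 8 each, Postn 4 and Wt1 3. The embryonic globin genes had 10 at Hbb-y and 2 at Hba-x. Sox2 had 3, Pax6 and Ptprc 1 each, and Alb, Afp and Myod1 had 0. The 10 genes with the most distal peaks were Zmiz1 (128), a transcriptional coregulator, Gse1 (122), Nav2 (111), Casz1 (109), a zinc finger factor of heart development, Bach2 (103), Foxp1 (100), Prdm16, Msi2 (97), an RNA-binding protein, Tead1 and Tspan9 (88). Of the other genes named here, the count moved by over 1.5 times in at least 1 replicate for Pecam1 (29 and 24), Kdr (14 and 21), Myh7 (12 and 9), Myh6 (6 and 2), Hbb-y (6 and 9), Wt1 (0 and 4), Hba-x (0 and 2), Sox2 (3 and 1), Actc1, Myl7, Pax6, Nppa and Ptprc.

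The question was whether heart genes lie near more distal peaks than other genes with as much room around them. Peaks over 1 kb from every TSS of a protein-coding gene were assigned to the nearest one within 100 kb, and lists were compared with 10000 random lists by a two-sided permutation test, adjusted over the 19 lists. Adjusted p was 0.00380 for cardiac transcription factors, sarcomere, ion handling and endothelial genes, where the unadjusted p of the transcription factors, 0.0002, is the smallest these permutations can give. For posterior Hox genes it was 0.0372. Not called were secreted signals (11.9 against 5.32, adjusted permutation p = 0.0830), neural (1.28 against 4.62, p = 0.0896), erythroid (3.44 against 1.39, p = 0.102), housekeeping (2.64 against 1.21, p = 0.102), other adult tissues (4.14 against 2.12, p = 0.144) and anterior Hox genes (2 against 0.811, p = 0.177). Adjusted permutation p was 0.504 for cushion (mean 7.90), 0.740 for second heart field (7.18) and endoderm (3.07), 0.832 for hepatocyte (3.20), 0.922 for epicardium (4.42) and skeletal muscle (2.83) and 0.931 for neural crest (4.50) and macrophage genes (2.60).

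With an equal number of each replicate's own peaks the transcription factors had means of 23.4 in replicate 1 and 22.6 in replicate 2, sarcomere genes 8.39 and 7.54, ion handling 14.5 and 14.0, and endothelium 11.4 and 11.2. The means of these 4 lists moved by over 1.5 times with the number of peaks, the transcription factors to 10.6 at the median signal and 43.6 in the pooled list, and all 4 calls held in each alternative tried. The posterior Hox call ended in 6 alternatives, among them without replicate 2 (mean 0.125, adjusted permutation p = 0.192) and in the pooled list (mean 0.375, p = 0.0917), and calls were gained for neural genes without replicate 1 (mean 0.833, p = 0.0279), anterior Hox genes without replicate 2 (mean 3.33, p = 0.0448) and secreted signals with a limit of 500 kb (mean 17.9, p = 0.0304), while the erythroid mean was 2.13 without replicate 2 (p = 0.567).

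**Figure D4:**
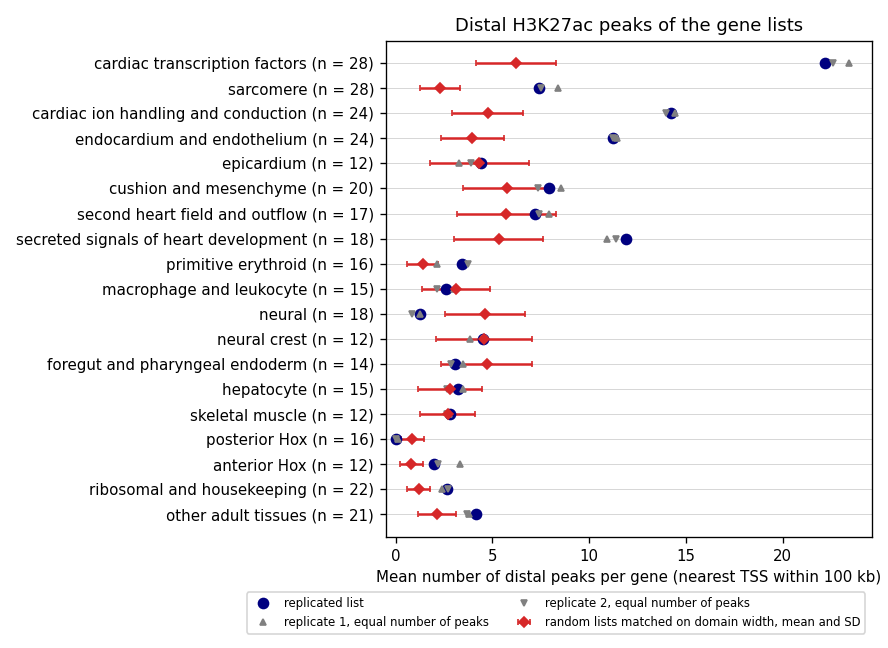
Mean number of distal peaks per gene (x axis) for each gene list (y axis, n genes): circles for the replicated list, gray triangles for an equal number of each replicate's own peaks, and red diamonds with bars for the mean and SD of random lists matched on domain width. Cardiac transcription factors stand at 22.2, against a random mean of 6.21.

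Of the 28 cardiac transcription factors, 7 were the gene nearest to the midpoint of one of the 500 highest-ranked clusters of distal peaks: Tead1 (rank 25), Prdm16 (53), Nkx2-5 (94), Tbx5 (127), Gata5 (206), Meis1 (361) and Hopx (448). The cluster of Nkx2-5 spanned 60297 bp at 17:26835802-26896098 and joined 25 peaks, and that of Tbx5 spanned 35891 bp at 5:119791981-119827871. Sarcomere genes nearest to a cluster by this rule were Actn2 (248), Myl2 (253), Tpm1 (296) and Ldb3 (304), and ion handling genes were Cacna1h (96), Id2 (246), Kcnq1 (274) and Hcn4 (416). Among housekeeping genes it was Actb (270), Eef1a1 (447) and Hprt (454). Of these clusters, those of Hopx, Myl2, Tpm1 and Hprt overlapped one of the 500 highest of replicate 2 only, and that of Id2 overlapped none of either replicate, while the others overlapped both. A gene that overlapped a cluster without being nearest to its midpoint was not counted. Tnni1 and Tnnt2 of the sarcomere list overlapped the cluster at rank 39, whose nearest gene was Phlda3. Kcnq1 also overlapped the cluster at rank 26, whose nearest gene was Cdkn1c.

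The highest-ranked cluster spanned 207150 bp at 2:30586427-30793576, joined 72 peaks and lay nearest to Cstad. Clusters of Gse1 and Zmiz1 followed with 134 and 143 peaks. Ranks 4 and 7 lay nearest to Smad6 and Smad7, the inhibitory SMADs that limit BMP and TGF-beta signalling, over spans of 269394 bp and 278531 bp. The other nearest genes among the 20 highest were, in order of rank, Zfp36l1, which promotes mRNA decay, Msi2, Slc38a10, Frmd8, Qk, an RNA-binding protein of muscle splicing, Mrpl23, Pim1, a kinase, Tex44, Prex1, Disc1, Foxl1, Tmem189, Cxxc5, Chd2 and Tspan9. The nearest gene need not be the gene that a cluster acts on, and the promoter peak of Tex44 itself, which also covered a TSS of Nmur1, had a signal of 3.32.

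The comparison asked which gene lists lie next to the clusters of distal peaks with the largest total of signal times width. Joining 71561 distal peaks close to each other gave 19865 clusters, ranked by the sum of signal times width, and the 500 highest held 20.1% of distal peaks over a median span of 74396 bp. Of these 500, 417 overlapped one of the 500 highest of replicate 1, 440 one of replicate 2, and 381 both. Random lists were matched on room within the distance limit of distal peaks, whereas clusters had no limit. The p of clusters therefore do not account for room beyond it. The share of genes nearest to one of the 500 was 25% for cardiac transcription factors (random 4.55 ± 3.88 SD, adjusted permutation p = 0.00380), 14.3% for sarcomere genes (1.66 ± 2.41, p = 0.0127) and 13.6% for housekeeping genes (0.949 ± 2.06, p = 0.0127). It was 16.7% for ion handling genes (3.70 ± 3.88, adjusted permutation p = 0.106), 9.52% for other adult tissues (p = 0.393), and with p = 1 each 11.1% for secreted signals, 6.67% for hepatocyte, 5.88% for second heart field, 4.17% for endothelium and 0% for the other 10 lists. Among lists not called, leaving out 1 replicate moved the share by over 1.5 times for endothelium (3 of 24 without replicate 1), secreted signals (5.56% without replicate 1), second heart field (11.8% without either), hepatocyte (0% without replicate 2), cushion (5%) and endoderm (7.14%) without replicate 1, and anterior Hox genes (8.33% without replicate 2), and none of these was called. Transcription factors were the only list called in all 12 settings, with 39.3% without replicate 2, while sarcomere genes were lost without replicate 2 (10.7%, adjusted permutation p = 0.115), in the pooled list (10.7%, p = 0.140), at stitching distances of 5 kb (10.7%, p = 0.0674) and 25 kb (10.7%, p = 0.160) and with 250 clusters (3.57%, p = 1). Housekeeping genes were at 0% in the pooled list, when ranked by covered bases and with 250 clusters, and were lost in 5 other alternatives (4.55 to 9.09%, adjusted permutation p from 0.129 to 1), whereas ion handling genes were called at 25 kb (20.8%, p = 0.0475) and with 1000 clusters (29.2%, p = 0.0101).

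Binding motifs of MEF2 and TEAD factors, which drive muscle genes and growth, were more enriched at distal peaks than all of their anagrams. The MEF2 consensus lay within 250 bp of the summit in 1.56% of 71554 distal peaks and in 0.751% of 87353 flanking windows, a ratio of 2.08 where 200 anagrams reached at most 1.34. TEAD stood at 10.4% against 7.78%, a ratio of 1.34 with anagrams up to 1.23. The GATA motif had a ratio of 0.867 and exceeded all 29 of its anagrams, whose highest was 0.778. ETS had the highest ratio, 2.20, with 1 anagram as high.

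The question was which factors' motifs mark the distal peaks of this tissue. In two-sided permutation tests against anagrams of equal CpG number, 0 of 19 motifs passed after Benjamini-Hochberg adjustment, and 7 had an unadjusted p under 0.05. Adjusted p can fall under 0.05 only where at least 4 motifs have a low p, and GATA (29 anagrams, smallest p 0.0667) and homeobox (13 anagrams, smallest p 0.143) could not pass a permutation test even unadjusted. For MEF2 and TEAD the unadjusted permutation p was 0.00995, the smallest that 200 anagrams can give, and the adjusted p was 0.0945. Adjusted permutation p was 0.108 for ETS, AP-1 (ratio 1.20), FOX (0.983), RUNX (0.899) and HNF1 (0.827), 0.158 for GATA, 0.231 for the SRF CArG box (1.01) and 0.241 for MEIS (1.32) and NR2F (1.28). For NKX (0.905) it was 0.494, and for TBX (0.953), the HAND and TWIST E-box (1.02), SOX, homeobox, POU, HNF4 and NEUROD motifs it lay between 0.347 and 0.917. Among replicated peaks that overlap both replicates' lists, an alternative chosen after seeing the data, 4 motifs were called at an adjusted permutation p of 0.0473, namely MEF2 (2.17), TEAD (1.37), SRF CArG (1.04) and HNF1 (0.824). Since a call needs 4 motifs with a low p, those of MEF2, TEAD and SRF CArG also rest on HNF1. That motif was rare, in 21 of 71554 peak windows and 31 of 87353 flanks of the main set, and its ratio lay under 1. Within 100 bp of the summit the MEF2 ratio was 0.933, still above its anagrams, and TEAD at 1.24 had 1 anagram as high, and the HNF1 ratio was 0.457 without replicate 1 and 0.391 at the median signal.

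**Figure D5:**
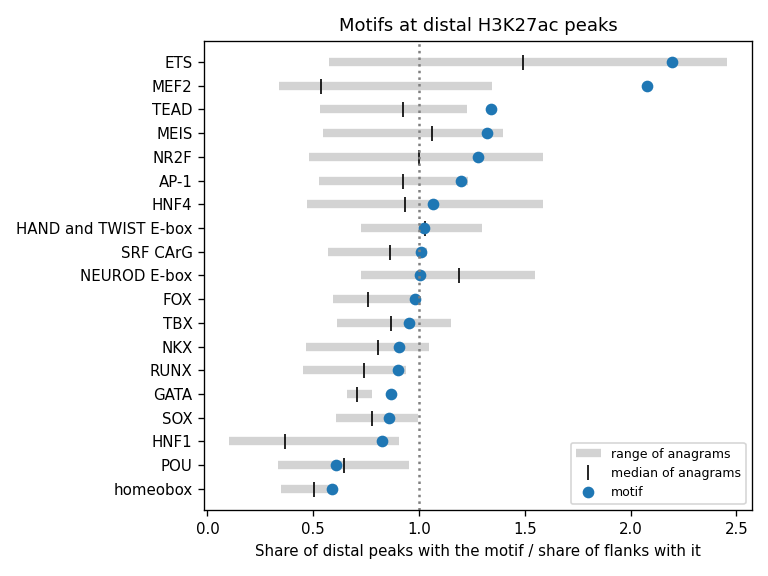
Ratio of the share of distal peaks with a motif to the share of flanking windows with it (x axis) for 19 motifs (y axis): circles for the motif, gray bars for the range of its anagrams, ticks for their median, and a dotted line at 1. MEF2 at 2.08 and TEAD at 1.34 lie above the ranges of their anagrams, which end at 1.34 and 1.23.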

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

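Neither value below was tested, and both were counted after the lists had been seen. On unplaced scaffolds, which the comparisons leave out, the replicated list held 7 peaks, with signals from 2.12 to 27.9. The pooled list held 770 peaks outside the replicated list that overlapped a peak of both replicates by at least 1 bp. None of the 108727 pooled peaks outside the replicated list overlapped both replicates over 50% of either region, whereas 68580 of the 91850 replicated peaks did and 23270 did not. The scaffold peaks lie outside every comparison, and the 770 peaks lie outside the replicated list that the main comparisons use and enter only where the pooled list is an alternative. No explanation was tested.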

How the results depend on the processing

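Restriction to peaks that overlap both replicates' lists, and a distal class counted from TSSs of every gene type, were tried only after the data had been seen. All 12 alternative values of the replicate overlap moved. The shares of replicate 1 in replicate 2 and of replicate 2 in replicate 1 were 75.6% and 47.4% at or above the median signal, 31.0% and 23.0% with 50% of both regions shared, 64.7% and 38.8% with 50% of either, 65.95% and 52.8% with equal numbers of peaks, 88.6% and 80.7% with the 20000 highest-ranked, and 76.5% and 49.5% at a −log10 p of at least 5. The promoter share of peaks was 34.1% at or above the median signal, 14.6% in the pooled list, 26.5% for peaks that overlap both replicates' lists, 19.7% with windows of 500 bp, 26.5% with 2 kb and 28.8% by covered bases, and it ranged from 22.6% to 24.9% with 1 replicate left out. The number of lists called for clusters fell from 3 to 1 in the pooled list, with stitching at 5 kb and with 250 clusters. Housekeeping genes fell below their random mean, to 0%, in the pooled list, when ranked by covered bases and with 250 clusters. The number of motifs called rose from 0 to 4 for peaks that overlap both replicates' lists. A wider window or more shared bases changes a share by its own construction, and for the other changes the cause was not tested.

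The number of lists called for promoter peaks ranged from 11 to 14 over the alternatives against 14, and 7 lists were called in all 9 settings. Of 152 promoter results for single lists, 12 lost and 3 gained a call and 137 stayed as they were. For distal peaks 6 of 171 lost and 3 gained a call and 162 stayed, and 4 lists were called in all 10 settings. For clusters 13 of 209 lost a call, the 3 at 0% included, 2 gained one and 194 stayed. For motifs 4 of 152 gained a call and 148 stayed uncalled, which says little where fewer than 4 motifs have a low p. No peaks overlapped within a list, so counting peaks one by one equals the values given and was not run apart. Depth is unknown, and peaks of low signal overlapped less often between the replicates than those of high signal, which limits counts that rest on weak peaks. No paired analysis was possible because there is 1 group.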

Other observations

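Noncoding genes stood inside several of the highest-ranked clusters, whose nearest protein-coding gene gives no hint of them. The cluster at rank 9, 19:5786613-5852994, held Malat1 and Neat1, the nuclear RNAs of speckles and paraspeckles. Rank 11, 7:142544601-142613850, held no protein-coding gene but the imprinted H19 with its microRNA Mir675, and Nctc1, and joined 19 peaks. Rank 21, 18:61609188-61697723, held Carmn and Bvht, noncoding RNAs of the cardiac lineage, with the smooth muscle microRNAs Mir143 and Mir145a, and a peak of 20653 bp. At Hand2 the peak of 25422 bp also covered the start of Hand2os1, a noncoding gene on the opposite strand. These regions were chosen after their values were seen.

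The tests of CpG content and of TSS number on parts of the lists, and the count of peaks per gene on chromosome X, were chosen only after the result was seen. The design has 1 group, so no biological explanation was tested for any of the patterns.

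Heart lists carried promoter peaks in 98.2% of 165 genes and the 8 lists of other tissues in 44.7% of 123. Random lists matched on CpG ratio gave 74.0% and 66.2%, and those matched on the number of annotated TSSs 68.3% and 60.3%. Each permutation p was 0.0002, the smallest possible, so neither property alone accounts for the pooled share of either set. Single lists of other tissues differed. Against CpG-matched lists only neural (38.9% against 92.9%) and posterior Hox genes (25% against 91.7%) passed among these 8. Hepatocyte (53.3% against 52.3%) and skeletal muscle genes (50% against 47.5%) lay close to theirs, and endoderm and neural crest genes lay lower without passing. Against TSS-matched lists only macrophage and other adult tissue genes passed. For macrophage and adult tissue lists (33.3% against 39.4%, permutation p = 0.480) CpG content may account for the low share. Neural and posterior Hox genes, which singly lay within lists matched on TSS number (adjusted p 0.236 and 0.160), together lay below them (32.4% against 51.1%, permutation p = 0.0276). Both lists were put together after their single results had been seen, and posterior Hox genes lie side by side and were treated as separate draws. The p of the pair may therefore be too small and does not decide the part of TSS number. For the transcription factor, second heart field and secreted signal lists together (98.3% against 90.1%, permutation p = 0.0148) the part of CpG content stays undecided, since matched random lists reached 100% and none of the 3 lists passed singly (adjusted p from 0.109 to 1).

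Promoter peaks of cardiac transcription factors had a median width of 6628.5 bp in the replicated list, 2996 bp in replicate 1 and 5921.5 bp in replicate 2, against 1151 and 1471 bp over all genes with a promoter peak in the replicates' lists. Higher peaks are wider, but genes matched on promoter signal had a mean of medians of 1951 bp, and genes matched on the number of annotated TSSs 1632 bp, with a permutation p of 0.0002 each, so neither alone accounts for the width. Sarcomere (4896 bp; 2688.5 and 4031.5 bp in replicates 1 and 2), ion handling (3465 bp; 2398 and 3075 bp) and secreted signal genes (2848 bp; 1586.5 and 2374 bp) were also wider than both kinds of matched genes (adjusted permutation p from 0.00076 to 0.00152). Endothelial, cushion, second heart field and anterior Hox genes were wider than signal-matched genes only (adjusted permutation p from 0.00076 to 0.0308), housekeeping genes were wider than TSS-matched genes only (0.0198), and skeletal muscle (380.5 against 856 bp, 0.0076) and other adult tissue genes (342 against 584 bp, 0.0342) were narrower than signal-matched genes and, like erythroid, neural, endoderm and posterior Hox genes, than TSS-matched genes (0.00095 to 0.0211). How the peak caller joins neighbouring peaks stays open.

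Chromosome X held 5.93 replicated peaks per Mb, against 26.8 to 59.9 on the 19 autosomes. A low number of genes is not enough, with 1.07 peaks per protein-coding gene against at least 2.83 on autosomes. Few marked promoters are not enough either, with 1.18 distal peaks per gene with a promoter peak against at least 3.68. Promoter peaks of CpG-rich genes had a median signal of 10.7 on X and 15.2 to 17.6 on autosomes. Lower read coverage or fewer acetylated copies of X in pools of mixed sex could bring this. Whether coverage would lower the signal depends on its scale, which is not given. These could not be separated because read coverage was not analysed here. Distal peaks went the other way, with a median signal of 3.68 on X and 3.52 to 3.61 on autosomes. Whether a threshold of the caller on peak height brings this was not tested.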
